A study of Homo sapiens with 37 samples.

How the data were processed

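The series holds 37 samples: 27 precipitated libraries in 13 groups and 10 inputs. Per the labels, NEUROG2 and SOX4 were precipitated with a polyclonal antibody against the HA tag, and H3K27ac and H3K27me3 with antibodies against the marks. The submitters' processing notes name Bowtie 1.0.0, HOMER 4.7 and the genome build hg19. Each precipitated library has a deposited list of peaks, and each group a merged list. Per the file headers, the lists came from HOMER's peak finder with an input as control, and the lowest fold over input in them was 4.

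Per the file headers, the columns of a list are a tag count in the library and a tag count in the input for each peak, a normalized signal in tags scaled to 10000000 tags per library, a peak score, fold ratios over input and over the local background, and p-values. The merged lists deposited by the authors are unions of the lists of a group with the mean signal of the merged peaks, so they hold no new peak calls. Total tags per library were read from the headers. Reads and signal tracks were not used here.

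Groups followed the labels. All 27 lists were compared in pairs within an antibody for identical total tags and identical peaks. H3K27me3 replicate 2 of MRC5 and replicate 2 of N held 1 library, which was left out of the H3K27me3 comparisons because the lists do not say which group it belongs to. Neither the labels nor the headers tell whether replicates of a histone mark came from separate cultures. The MRC5 control differs from N in virus and in medium. No column of the sample annotation was left unused (0).

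Peaks of an antibody were merged into sites wherever they shared at least 1 bp. The tags of a library at a site were the sum over its own called peaks there, not over the whole interval. Tags at sites called in all libraries compared were tested with edgeR 4.0.16 (quasi-likelihood F test, TMM factors on the total tags of the headers) at a Benjamini-Hochberg adjusted p of 0.05 over all sites of a comparison. NEUROG2 was fitted with time and treatment as terms, and histone marks with group means. A fit with interaction terms asked whether the effect of the molecules differed between times. Sites called in at least 5 of 6 libraries of 1 treatment and at most 1 of the other were counted as mostly in that treatment. Histone regions were counted as gained or lost when called in both libraries of 1 group and neither of the other, beside the crossed splits of the same 4 libraries. Numbers of peaks were compared by 2-sided exact permutation within times or treatments.

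Sites called in both libraries of a NEUROG2 group or in at least 2 of the 3 SOX4 libraries were overlapped with each other and with histone regions by at least 1 bp. Expected overlaps came from 100 shuffles within chromosomes, with the highest coordinate in any list as the end of a chromosome and no gaps excluded, and from shuffles over the sites of all lists. Classes of sites were compared by 2-sided Fisher's exact tests.

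The tests, the alternatives and the rule for named sites were chosen before the data were examined. Added after that were the comparison of tags in peaks and of tags at shared sites between treatments, the classes of NEUROG2 sites in histone regions and SOX4 sites, the NEUROG2 and SOX4 sites in gained and lost regions, the correlation of effects across sites, and the left-out H3K27me3 library. The fits by day and the time changes within a treatment were not among the tests chosen beforehand. Nor were the H3K27ac tag test of NFD against MRC5 and the NEUROG2 sites in H3K27ac regions that rose or fell. The rule took, of the sites past the threshold that moved the same way in every pair of libraries, the 10 with the largest and the 10 with the smallest log2 fold change per comparison, and the 5 strongest sites of each factor. Values are printed for the first few, and the rest are summarised. For H3K27me3 only the first each way is printed. The parts of the rule that tie sites to genes, the 14 gene lists and the motif shares were not run, because no annotation or sequence of hg19 was used here, so sites are named by coordinates only. No test for single outlying samples was made, since groups held 2 or 3 libraries.

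Alternatives were DESeq2 1.42.0, limma 3.58.1 on log2 tags with missing libraries left out, total tags without TMM factors, tags per kb of called peak, at least 20 tags on average, only the groups compared, a replicate block, peaks at least 8-fold over input, an equal number of top peaks per list, centres within 200 bp or 50% of the shorter peak as overlap, the merged lists, peaks relative to total tags, and leaving out each library in turn. The minimum of 20 tags on average removed no site, so that setting repeated the main fits. Where a group was left with 1 library, it was assumed to vary like the others.

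Recovery was tested on simulated data with 200 changed sites. For NEUROG2 and H3K27ac that was far fewer than the data called between N and NFD. Fewer changed sites make the adjusted threshold stricter, so the rates may not carry over to the data. For NEUROG2 the fit found 77.6% of 1.5-fold changes and 100% of 2- and 3-fold changes, with 0.223% of unchanged sites called. For H3K27ac it found 5.97%, 59.7% and 98.5%, with 0.0590% of unchanged regions called. For H3K27me3 with 4 libraries it found 0 at each size and called 0 unchanged regions. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, and R 4.3.3 were used.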

Results

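MRC-5 is a line of human fetal lung fibroblasts. The cells received a lentivirus for NEUROG2, a neurogenic basic helix-loop-helix transcription factor, and chromatin immunoprecipitation with sequencing (ChIP-seq) recorded where the factor bound and how the chromatin was marked. N stands for cells with NEUROG2 in neuron induction medium. NFD stands for the same cells in that medium with 10 μM forskolin, an activator of adenylyl cyclase, and 1 μM dorsomorphin, an inhibitor of bone morphogenetic protein receptors and of AMPK. MRC5 stands for fibroblasts without the virus in serum medium. NEUROG2 was precipitated through its HA tag in N and NFD after 0.5, 1 and 2 days, with 2 libraries in each of these groups. SOX4, an HMG-box transcription factor, was precipitated through its HA tag from cells that also carried NEUROG2 and received both molecules, after 1 day (n = 3 libraries). Acetylated histone H3 lysine 27 (H3K27ac), a mark of active promoters and enhancers, and trimethylated lysine 27 (H3K27me3), the mark of Polycomb repression, were profiled in MRC5, N and NFD (n = 2 libraries each). The labels give 1 day for these histone samples, while their extraction text gives 2 days of treatment.

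Of the 37 samples, 27 carried a list of called peaks and 10 were inputs. Libraries held 47597154 to 56686501 tags for NEUROG2, 31869582 to 31987526 for SOX4, 34545959 to 42128073 for H3K27ac and 26350911 to 41377233 for H3K27me3. Normalised tags below are tags scaled to 10000000 tags per library, without TMM factors, while the log2 fold changes of the main fits include these factors. Tags at a site or region are those inside the peaks that a library called there, so called width enters the values. The lists held 26409 to 64511 peaks per library for NEUROG2, 8841 to 15291 for SOX4, 42900 to 51659 for H3K27ac and 9529 to 32387 for H3K27me3. The labels do not say that libraries of a group came from separate cultures, so every p-value measures only the spread between these libraries, which may be technical. All coordinates are those of build hg19.

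Libraries of a group shared most of their H3K27ac regions and few of their SOX4 peaks. The median share of a library's peaks that overlapped a peak of its replicate was 84.2% for H3K27ac (range 78.6 to 86.7%), 62.0% for NEUROG2 (21.8 to 80.1%), 51.8% for the NFD libraries of H3K27me3 and 15.9% for SOX4 (11.9 to 20.6%). Between groups, H3K27ac libraries of MRC5 shared 43.8 to 55.1% of their regions with those of N and NFD, while N and NFD shared 63.5 to 76.0% with each other. For NEUROG2 the median was 48.0% between treatments at any time and 50.4% between times of a treatment, so this measure did not set treatments apart from times. For H3K27me3, replicate 2 of MRC5 and replicate 2 of N were 1 library under 2 labels: both headers gave 38989279 total tags and 705748 candidate peaks, and all 3745 regions with the same coordinates carried the same number of tags. Even so, only 67.5% of the regions in its MRC5 list overlapped its N list, and 68.1% the other way round. The calling of a list thus changed its regions within 1 library. In the other 98 pairs of libraries of an antibody, at most 257 peaks had the same coordinates, and the total tags differed in every pair. Lists of NEUROG2 or SOX4 with unequal fixed peak widths could not share coordinates, so for those pairs only the totals tell libraries apart. The library under 2 labels was left out of the H3K27me3 comparisons, since its group is not known. The header of the NEUROG2 NFD 1-day replicate 2 list quotes the peak-finding command of replicate 1, but its total of 51421408 tags differs from the 48937580 of replicate 1, so both were used as labelled. The lists share 0 peaks of equal coordinates, but this could not be otherwise, since peaks were 186 bp wide in replicate 1 and 182 bp in replicate 2.

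The first comparison asked how forskolin and dorsomorphin changed NEUROG2 binding. NEUROG2 tags changed in both directions: among the 5572 sites called in all 12 libraries, tags rose with the molecules at 1025 and fell at 943, relative to the other shared sites. Changes were mostly under 2-fold, with 22 sites higher and 14 lower by more than that, and ranged from a log2 fold change of 1.63 to -1.35. The site with the strongest rise, on chromosome 3 from 182833919 to 182834306, went from 7.07 ± 1.20 normalised tags in N to 27.3 ± 7.28 in NFD (SD, n = 6 each), a log2 fold change of 1.63 (SE 0.14, adjusted p = 2.0e-13 by edgeR). Next came a site on chromosome 16 from 129044 to 129329, inside H3K27ac regions of all 3 conditions, with 11.7 ± 1.54 and 38.6 ± 6.33 normalised tags (log2 fold change 1.39, SE 0.11, adjusted p = 2.5e-14 by edgeR). A site on chromosome 9 from 140264650 to 140265010 rose from 7.41 ± 1.23 to 23.8 ± 7.58 (log2 fold change 1.36, SE 0.14, adjusted p = 4.2e-10 by edgeR).

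The 3 sites that fell most with the molecules all lay in H3K27ac regions of N that were not called in MRC5 or NFD. On chromosome 9 from 27414175 to 27414481 normalised tags went from 11.4 ± 3.36 to 5.54 ± 1.28 (log2 fold change -1.35, SE 0.16, adjusted p = 1.4e-08 by edgeR, n = 6 each). On chromosome 17 from 41899177 to 41899406 they went from 12.2 ± 3.44 to 6.02 ± 2.05 (log2 fold change -1.33, SE 0.15, adjusted p = 5.8e-09 by edgeR). On chromosome 11 from 92738497 to 92738765 they went from 13.2 ± 4.41 to 6.83 ± 1.61 (log2 fold change -1.26, SE 0.15, adjusted p = 1.6e-08 by edgeR). Of the 10 named sites with the largest rise, 7 lay in H3K27ac regions of NFD and 4 in those of N. For the 10 with the largest fall these numbers were 0 and 8.

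All of these tests came from edgeR's quasi-likelihood model with time and treatment as terms and Benjamini-Hochberg adjustment. On simulated data this model found 77.6% of 1.5-fold changes. The split between higher and lower depends on the scaling: with total tags alone as library size the median shared site lay 0.32 higher in NFD on the log2 scale, and the calls became 2000 higher and 85 lower.

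On average NFD libraries also carried more NEUROG2 signal, but no measure of this passed a correction for the number of tests. Of all tags, 3.28 ± 0.904% lay in called peaks in NFD against 2.22 ± 0.458% in N (SD, n = 6 each; 2-sided exact permutation p = 0.0463 within times). At the shared sites the mean was 14.5 ± 2.53 against 11.4 ± 2.39 normalised tags (2-sided exact permutation p = 0.0463). The number of peaks called, the measure chosen before the data were examined, was 44193 ± 12028 in NFD and 36034 ± 8829 in N, a difference within the spread of the libraries (2-sided exact permutation p = 0.231, 216 arrangements, smallest possible p 0.00926). The difference of 8158 peaks became 3150 without NFD 0.5-day replicate 1, 4677 without N 0.5-day replicate 1 and 13167 without NFD 0.5-day replicate 2. Both measures with an exact permutation p of 0.0463 belong to a family of 6, were added after the peak numbers were seen, and do not pass a correction for 6 tests. Even the smallest possible permutation p of 0.00926 would not pass a Bonferroni correction for 6 tests.

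**Figure D1:**
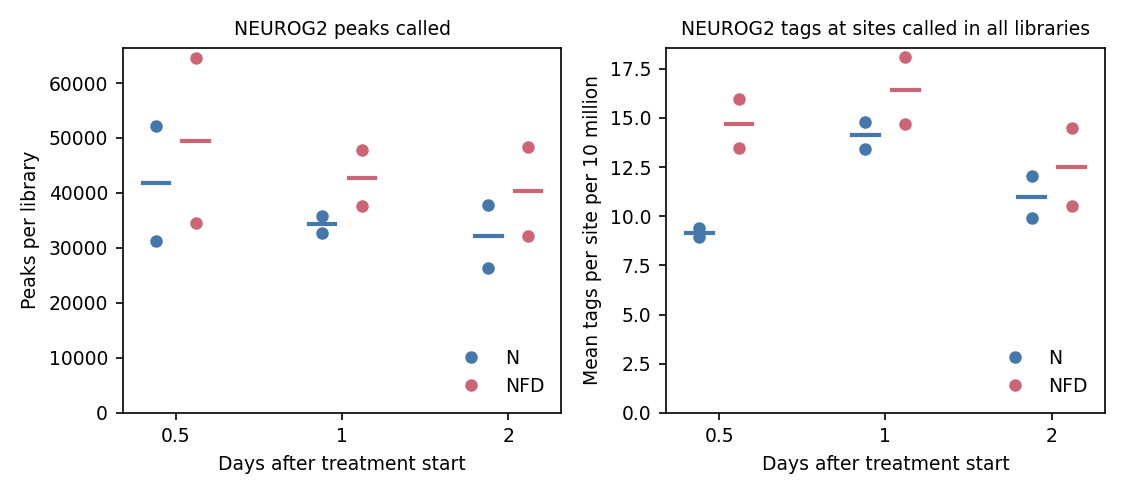
NEUROG2 peaks called per library (left) and mean NEUROG2 normalised tags at the 5572 sites called in all 12 libraries (right), against days after the start of treatment. Each dot is 1 library and each short line the mean of the 2 libraries of a group, and single libraries ran from 8.95 to 14.8 normalised tags in N and from 10.5 to 18.1 in NFD.

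Counted by presence of a called peak, more sites were on the NFD side. Of 179439 sites called in any library, 2714 were called in at least 5 of 6 NFD libraries and at most 1 of 6 N libraries, and 459 the other way round. In all 6 NFD libraries and no N library were 388 sites, against 40 in the reverse. With an equal number of top peaks in every list the counts were 1847 and 883. Without NFD 0.5-day replicate 1 the total of 3173 became 4836 and without its replicate 2 it became 5289, but with a library left out the rule asked for 4 of the 5 that remained, so library and rule changed together.

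The next comparison followed NEUROG2 binding over time. Between 0.5 and 2 days tags rose at 327 shared sites and fell at 352. The largest rise was on chromosome 11 from 133806418 to 133806724, at a site that SOX4 peaks also covered, from 4.75 ± 0.614 to 11.1 ± 1.90 normalised tags (SD, n = 4 each; log2 fold change 1.20, SE 0.21, adjusted p = 8.7e-05 by edgeR). A site on chromosome 3 from 51812025 to 51812281 rose from 6.95 ± 2.60 to 15.5 ± 4.95 (log2 fold change 1.19, SE 0.17, adjusted p = 3.4e-06 by edgeR). The largest fall was on chromosome 22 from 24577446 to 24577708, in an H3K27ac region of N, from 45.5 ± 15.5 to 18.1 ± 5.20 (log2 fold change -1.31, SE 0.13, adjusted p = 3.4e-10 by edgeR). On chromosome 13 from 110978640 to 110978914 tags fell from 15.6 ± 6.97 to 6.26 ± 2.47 (log2 fold change -1.27, SE 0.18, adjusted p = 3.4e-06 by edgeR).

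With tags per kb of called peak the time calls were 536 higher and 222 lower, with total tags alone 119 sites were called, and without NFD 2-day replicate 1 the count was 448. Numbers of peaks did not differ between times beyond their spread (exact permutation p = 0.470, 8100 arrangements). The effect of the molecules differed between times at 1 site by edgeR's interaction test (573 at an unadjusted p under 0.05), and at 0 by DESeq2 (211 at an unadjusted p under 0.05).

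The third comparison asked how NEUROG2 changed H3K27ac in fibroblasts. The mark changed at 8360 of the 15464 regions called in all 6 libraries: 4084 rose and 4276 fell from MRC5 to N, 2105 and 2175 of them by more than 2-fold. The strongest rise was on chromosome 2 from 178614115 to 178625891, from 16.3 ± 0.191 to 226 ± 23.8 normalised tags (SD, n = 2 each; log2 fold change 4.04, SE 0.14, adjusted p = 1.6e-05 by edgeR), at a NEUROG2 site. The region on chromosome 10 from 52876048 to 52883858 rose from 15.5 ± 1.04 to 194 ± 5.77 (log2 fold change 3.90, SE 0.16, adjusted p = 1.6e-05 by edgeR), and that on chromosome 3 from 106528738 to 106540315 from 11.1 ± 0.168 to 133 ± 52.5 (log2 fold change 3.87, SE 0.38, adjusted p = 0.00013 by edgeR).

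The strongest falls were at regions without a NEUROG2 site. The tags given for a region are those inside the peaks that each library called in it, not of the whole interval. On chromosome 5 from 52710419 to 52728454 normalised tags went from 655 ± 2.23 to 21.3 ± 0.361 (SD, n = 2 each; log2 fold change -4.68, SE 0.18, adjusted p = 1.6e-05 by edgeR). On chromosome 10 from 94570878 to 94584812 they went from 449 ± 6.05 to 17.5 ± 0.258 (log2 fold change -4.42, SE 0.21, adjusted p = 1.8e-05 by edgeR), and on chromosome 4 from 139188188 to 139200705 from 368 ± 8.40 to 15.7 ± 3.61 (log2 fold change -4.29, SE 0.16, adjusted p = 1.6e-05 by edgeR). Of the 10 named regions with the largest rise 9 held a NEUROG2 site of N, against 0 of the 10 with the largest fall.

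H3K27ac regions were also gained and lost outright. From MRC5 to N, 16540 regions were called in both N libraries and neither MRC5 library and 13348 the other way round, while the 2 crossed splits of the same 4 libraries gave 570 and 714 in all. The labels give 1 input per group. Here and in the later comparisons the crossed splits therefore cannot show differences that come from the inputs. Which of these was larger depended on the lists: 12797 were gained and 13025 lost with an equal number of peaks per list, and 2745 and 3952 with peaks at least 8-fold over input. Without MRC5 replicate 1 or 2 they were 18192 and 19174 or 17869 and 18373, where a single MRC5 library decided presence, which loosens the rule. Of the gained regions 40.6% held a NEUROG2 site of N at 1 day, against 1.39% of the lost ones (odds ratio 48.4 by Fisher's exact test) and 26.7% of the regions in all 4 libraries. Among regions of middle width these shares were 42.0% gained and 1.16% lost. MRC5 and N differ in virus and in medium alike, so these changes cannot be assigned to NEUROG2 alone. The split of higher and lower regions moved with the scaling: 2555 and 5537 with total tags alone, where the median region lay at -0.27 on the log2 scale, and 5312 and 1315 with tags per kb of called peak, where it lay at 0.21.

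**Figure D2:**
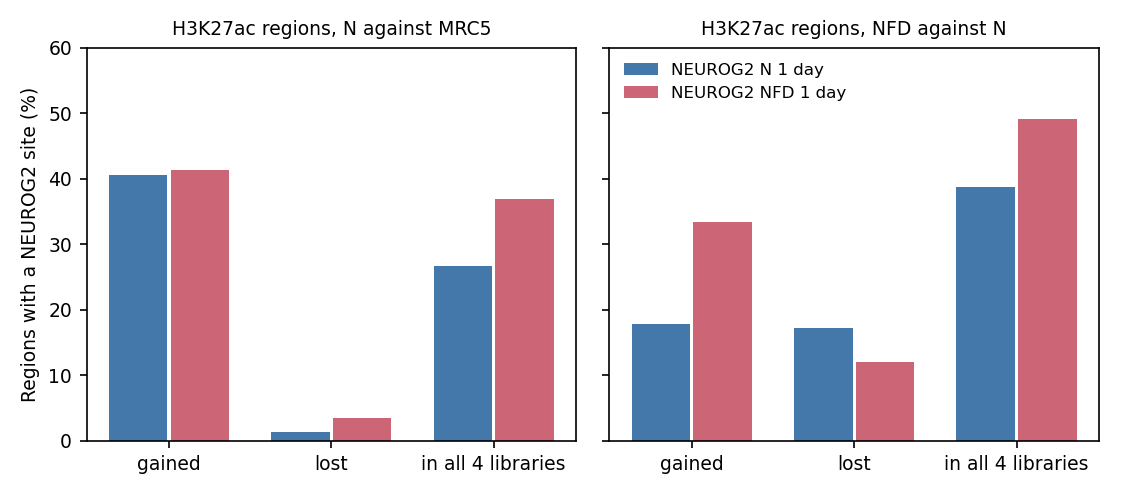
Share of H3K27ac regions (percent) that held a NEUROG2 site called in both 1-day libraries of N or of NFD, for regions gained, lost or called in all 4 libraries, from MRC5 to N (left) and from N to NFD (right). From MRC5 to N 40.6% of gained, 1.39% of lost and 26.7% of regions in all 4 libraries held a NEUROG2 site of N; from N to NFD 33.4% of gained, 12.1% of lost and 49.1% of regions in all 4 libraries held a NEUROG2 site of NFD.

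Forskolin and dorsomorphin then changed H3K27ac further, in both directions. From N to NFD 2521 shared regions rose and 3378 fell, 658 and 1732 of them by more than 2-fold. The strongest rise was on chromosome 22 from 50906815 to 50914378, from 20.4 ± 2.40 to 187 ± 55.8 normalised tags (SD, n = 2 each; log2 fold change 3.08, SE 0.26, adjusted p = 0.00033 by edgeR), at a NEUROG2 site of NFD that was not called in N. On chromosome 21 from 45145251 to 45149807 tags went from 19.9 ± 1.22 to 141 ± 6.77 (log2 fold change 2.70, SE 0.15, adjusted p = 0.00016 by edgeR). On chromosome 5 from 172355320 to 172372675, which held NEUROG2 and SOX4 sites, they went from 57.1 ± 9.58 to 376 ± 3.69 (log2 fold change 2.60, SE 0.12, adjusted p = 0.00011 by edgeR), and per kb of called peak this change was -0.14 with an adjusted p of 0.510 by edgeR.

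The strongest falls went from 208 ± 41.2 to 18.2 ± 4.29 normalised tags on chromosome 12 from 58956953 to 58970924 (SD, n = 2 each; log2 fold change -3.63, SE 0.17, adjusted p = 0.00011 by edgeR), from 122 ± 28.7 to 13.5 ± 4.68 on chromosome 7 from 106403705 to 106422664 (log2 fold change -3.27, SE 0.22, adjusted p = 0.00021 by edgeR) and from 207 ± 5.47 to 24.2 ± 11.1 on chromosome 15 from 71079144 to 71096921 (log2 fold change -3.24, SE 0.25, adjusted p = 0.00026 by edgeR). All 3 held NEUROG2 sites of both treatments. Outright, 5310 regions were gained and 8471 lost, against 1314 and 1166 in the crossed splits. With an equal number of peaks per list 6053 were gained and 6263 lost, so most of the excess of losses was not seen with equal lists. Of the gained regions 33.4% held a NEUROG2 site of NFD and of the lost ones 12.1% (odds ratio 3.65, Fisher's exact p = 3.5e-197), and both shares were below the 49.1% of regions called in all 4 libraries. For NEUROG2 sites of N the shares were 17.9% and 17.2% (Fisher's exact p = 0.322), against 38.7% of regions in all 4. SOX4 sites lay in 1.90% of gained and 0.626% of lost regions (Fisher's exact p = 1.5e-11), against 6.77% of regions in all 4.

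Leaving out NFD replicate 2 took the 5899 calls between N and NFD to 3576 (1223 higher, 2353 lower), and leaving out N replicate 1 or 2 took the gained and lost regions from 13781 to 22034 or 21707, where the rule was looser as well, since a single N library decided presence. Whether falls outnumbered rises depended on the scaling: with tags per kb of called peak 1400 regions were higher and 3078 lower, while with total tags alone 2663 were higher and 2508 lower and the median region lay at 0.13 on the log2 scale.

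For H3K27me3, 4 distinct libraries remained, 1 each of MRC5 and N and 2 of NFD, and the single libraries were assumed to vary as the NFD pair did. The log2 fold changes below include TMM factors, 0.574 for the N library, and the normalised tags do not. Ratios of the printed tags therefore differ from the log2 fold changes. Of 2944 shared regions, 12 rose and 33 fell from MRC5 to N, and 208 rose and 76 fell from N to NFD by edgeR. The largest changes between MRC5 and N were at chromosome 6 from 41436014 to 41454561, with 14.0 and 139 normalised tags (log2 fold change 4.34, SE 0.45, adjusted p = 0.029 by edgeR), and at chromosome 1 from 201360590 to 201374198, with 375 and 14.5 (log2 fold change -3.65, SE 0.34, adjusted p = 0.029 by edgeR). Between N and NFD they were at chromosome 5 from 139423147 to 139452462, with 16.4 in N and 462 ± 21.5 in NFD (SD, n = 2; log2 fold change 3.73, SE 0.27, adjusted p = 0.018 by edgeR), and at chromosome 5 from 1871731 to 1892131, with 235 and 33.0 ± 2.52 (log2 fold change -3.91, SE 0.23, adjusted p = 0.018 by edgeR).

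These H3K27me3 calls rest on few and unequal libraries, and their number and direction moved with the method; on simulated data the model found 0 of the 1.5-, 2- and 3-fold changes. The N library had 9529 regions and 3.47% of its tags in them. With total tags alone the splits were 11 higher and 483 lower from MRC5 to N (median region -1.06 on the log2 scale) and 961 and 13 from N to NFD (median 1.12). Tags per kb of called peak reversed both, to 2095 higher and 0 lower (median 0.77) and to 0 higher and 2724 lower (median -0.93). Limma on sites missing in some libraries called 0 in either comparison (1487 and 1972 at an unadjusted p under 0.05), and edgeR with equal lists called 0 in either (168 and 225), while DESeq2 called 125 and 249. Without the MRC5 library the count from N to NFD was 436. Outright, 10680 regions were called in both NFD libraries but not in N and 3012 in N only, 13692 in all. The crossed splits gave 17309 and 11582, so this count exceeded 1 of them and not the other.

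The chromatin at NEUROG2 sites was then compared between conditions. NEUROG2 sites lay in H3K27ac regions of induced cells more often than in those of fibroblasts. Of 22761 sites called in both N libraries at 1 day, 25.1% lay in H3K27ac regions of MRC5, 63.7% in those of N and 60.9% in those of NFD. For the 29166 sites of NFD these shares were 30.3%, 59.8% and 65.8%. With peaks at least 8-fold over input they fell to 4.96%, 13.0% and 12.9% for N and to 6.31%, 12.5% and 16.1% for NFD, and with equal lists the N sites lay in H3K27ac regions of N at 53.7% and of NFD at 62.4%. With the main lists, sites shuffled within their chromosomes gave 3.84 to 4.92% on average over 100 shuffles, and shuffling over the sites of all lists gave 19.4 to 24.5%. With peaks at least 8-fold over input the means shuffled within chromosomes were lower too. They were 1.11%, 0.530% and 0.603% for N and 1.13%, 0.523% and 0.603% for NFD. H3K27me3 regions of MRC5, N and NFD held 3.26%, 3.15% and 2.23% of the N sites and 3.47%, 2.99% and 2.27% of the NFD sites, against 1.89%, 0.750% and 2.21% (N sites) and 1.92%, 0.749% and 2.21% (NFD sites) when shuffled within chromosomes. Shuffled over the sites of all lists the shares were 4.66%, 2.18% and 4.79% for N and 4.69%, 2.18% and 4.80% for NFD. Overlap with H3K27me3 of MRC5 and NFD was below that second background, but not below the shuffles within chromosomes. Its direction thus depended on the background, and no avoidance of H3K27me3 can be read from it. Overlap with H3K27me3 of N was above both backgrounds. MRC5 and N were each represented by 1 H3K27me3 library here.

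Sites that NEUROG2 occupied more with the molecules lay more often in chromatin that was already acetylated in fibroblasts. H3K27ac regions of MRC5 held 34.8% of the 1025 raised sites and 18.6% of the 943 lowered ones (Fisher's exact p = 3.1e-16, adjusted 6.2e-16 over 12 tests). For sites called mostly with NFD and mostly with N the shares were 36.4% and 8.06% (Fisher's exact p = 1.1e-39, adjusted 3.4e-39). H3K27ac of NFD covered 90.5% of raised and 68.7% of lowered sites, and H3K27ac of N covered 72.1% and 80.7%. Of the 3604 shared sites not called different, 27.8% lay in H3K27ac regions of MRC5, 80.5% in those of N and 85.3% in those of NFD. In regions of N the lowered sites were thus near this baseline and the raised sites below it. SOX4 sites coincided with 6.33% of the sites not called. SOX4 sites coincided with 9.27% of raised and 3.50% of lowered sites (Fisher's exact p = 2.0e-07, adjusted 3.4e-07). These tests count sites of a genome and not replicates.

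**Figure D3:**
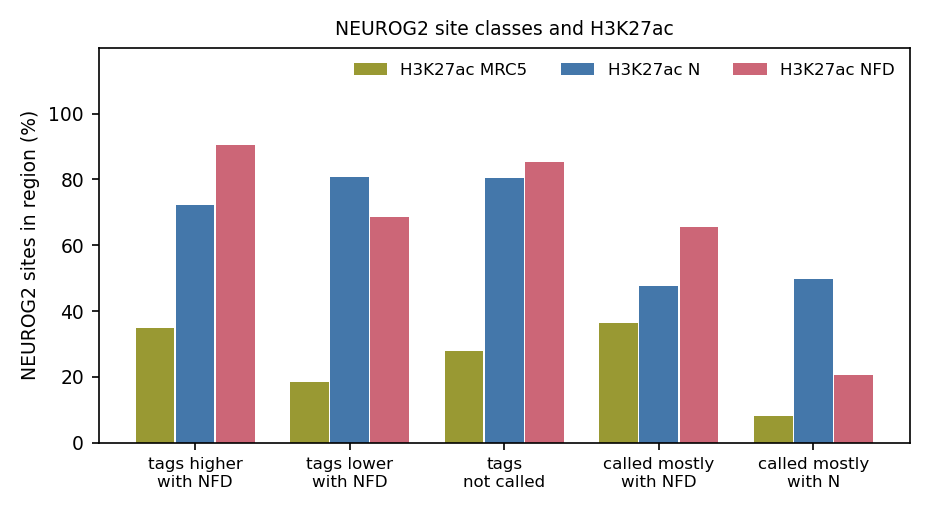
Share of NEUROG2 sites (percent) inside H3K27ac regions called in both libraries of MRC5, N or NFD, by class of site: shared sites whose tags were higher, lower or not called different with NFD, and sites called mostly in NFD or mostly in N libraries. In MRC5 regions lay 34.8% of raised, 18.6% of lowered, 36.4% of mostly-NFD and 8.06% of mostly-N sites.

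At 1827 shared NEUROG2 sites that lay in a single shared H3K27ac region (1682 regions), the effects of the molecules on both signals went together across sites, with Pearson's r of 0.493 and Spearman's rho of 0.499. Sites are not independent replicates, so no p is given. Of 419 sites where NEUROG2 rose, H3K27ac rose at 194 and fell at 20. Of 204 sites where it fell, H3K27ac rose at 9 and fell at 114.

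The last comparison asked how far SOX4 and NEUROG2 met at the same sites. Of 3487 sites called in at least 2 of the 3 SOX4 libraries, 960 (27.5%) overlapped a NEUROG2 site of NFD at 1 day and 20.6% overlapped one of N. The share was 9.89%, 10.6% and 11.8% for all peaks of the single SOX4 libraries. With other lists of both factors it was 11.6% (merged lists) and 10.8% (peaks at least 8-fold over input), which were 15.0 and 57.4 times their shuffled means, against 58.9 times for the 27.5%. In the other direction, 3.29% of the 29166 NEUROG2 sites of NFD overlapped a SOX4 site. Shuffling the SOX4 sites within chromosomes gave 0.468 ± 0.118% (SD over 100 shuffles, highest 0.889%), and shuffling over the sites of all lists gave 11.5%, so the observed share was 2.39 times that. H3K27ac regions of MRC5, N and NFD held 45.9%, 57.4% and 61.5% of the SOX4 sites. The strongest SOX4 site, on chromosome 7 from 90893611 to 90893821, carried 348 ± 41.8 normalised tags (SD, n = 3) and lay in H3K27ac regions of all 3 conditions with no NEUROG2 site. It was followed by chromosome 17 from 79367729 to 79367935 (259 ± 14.7) and chromosome 1 from 93544612 to 93544822 (227 ± 43.4), the latter at a NEUROG2 site of NFD. The strongest NEUROG2 sites over all 12 libraries were on chromosome 9 from 45352157 to 45352388 (54.4 ± 14.7 normalised tags, n = 12) and from 66493558 to 66493762 (47.0 ± 13.2).

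Only 1119 SOX4 sites were called in all 3 libraries, and the antibody for both factors was the same polyclonal anti-HA antibody, with no precipitation from cells without an HA tag analysed here. Sites that bind the antibody without a factor would count as shared. Whether the NEUROG2 in the SOX4 cells also carried the HA tag is not established here. If it did, the antibody would draw NEUROG2 sites directly in the SOX4 libraries.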

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

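The tests of a copy-number gain and of foreign DNA were chosen only after the result was seen.

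The effect of forskolin and dorsomorphin on NEUROG2 tags differed between times at 1 site, on chromosome 16 from 87397546 to 87398049 (adjusted p = 0.028 by edgeR's interaction test, 573 sites at an unadjusted p under 0.05). In N the site carried 9.05 ± 2.22, 6.49 ± 0.195 and 4.39 ± 1.11 normalised tags at 0.5, 1 and 2 days, and in NFD 12.7 ± 2.25, 17.8 ± 2.88 and 17.3 ± 7.46 (SD, n = 2 each). DESeq2 called 0 sites (211 at an unadjusted p under 0.05). edgeR called 1 site, not traced to this position, without N 0.5-day replicate 2, without N 2-day replicate 1 or without NFD 2-day replicate 2, and 0 without any other of the 12 libraries (469 to 766 at an unadjusted p under 0.05).

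H3K27me3 replicate 1 of N held a tower of tags on chromosome 6 from 21594162 to 21596721. It entered the counts of called regions as 1 region of N, but not the tag tests, which used shared regions only. This region of 2560 bp carried 32906 tags, 3311 times its input, where the next highest fold in that list was 23.4. It took 12854 tags per kb against 1915 in the next region and a median of 44.2. A copy-number gain in the cells would raise the input as well, and a fold of 3311 over input argues against that. Carry-over from an H3K27ac library would bring its strongest regions along, and only 9 of the 100 strongest H3K27ac regions of N were called in this library. Foreign DNA in this library, such as a plasmid insert, may be the source: 0 of the 5 other H3K27me3 lists held the region, but this cannot be told apart from other sources without reads, and no biological explanation was tested. The region was called in 17 of the 27 lists, with at most 635 tags elsewhere.

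The same library listed 2 mitochondrial regions with 20298 tags in all, 4.16- and 4.24-fold over input, and no other list held one (0).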

How the results depend on the processing

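The settings that keep all 6 H3K27me3 lists as labelled were chosen only after the data were seen. Over 40 results and 420 values under alternatives, 269 stayed within the tolerance, 143 moved and 8 reversed. The minimum of 20 tags on average removed no site, so its values repeat the main fits and are among the 269 without testing them. The tolerance was a factor of 1.5 for counts, 10 percentage points for the share of calls in 1 direction, 1 SD between libraries for overlaps and agreement, and the same side of the threshold for tests, so it is wide for counts and narrow for overlaps, and a share that crossed 50% by moving less than 10 points is among the 269. A setting in which a named site was not tested gave no value for it and is not counted. Among the values that exist, those of the 20-tag setting included, named sites kept their direction and call in all 396 and 416 for NEUROG2 treatment and time. For H3K27ac they did so in 293 (3 no longer past the threshold) and 280 (6 no longer past it, 1 reversed), and for H3K27me3 in 90 (67 and 10) and 106 (71 and 10). Where a value moved or reversed the cause was not tested, except that peaks at least 8-fold over input and equal lists leave fewer sites. The IP numbers do not pair the libraries: between groups, deviations of replicates with the same number correlated at -0.0348 to 0.0911 for NEUROG2 and -0.147 to 0.180 for H3K27ac, and with a replicate block the counts were 1956 (NFD against N), 688 (time), 2 (treatment by time, 587 at an unadjusted p under 0.05), 8043 and 5447 (H3K27ac, N against MRC5 and NFD against N). Not run were gene distances and motif windows, and for H3K27me3 the 8-fold tag test, the block on 4 libraries and the merged lists, which could not give values.

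With total tags and no TMM factor, 95.9% of NEUROG2 treatment calls were higher, 119 sites changed with time, and 8 showed treatment by time. Of H3K27ac calls from MRC5 to N 31.6% were higher. H3K27me3 gave 494 calls (2.23% higher) from MRC5 to N and 974 (98.7% higher) from N to NFD.

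With tags per kb of called peak, 70.7% of NEUROG2 time calls were higher (reversed) and 3 sites showed treatment by time. Of H3K27ac calls 80.2% were higher from MRC5 to N (reversed) and 31.3% from N to NFD, and chromosome 5 from 172355320 reversed to -0.14. H3K27me3 gave 2095 calls, 100% higher (reversed), from MRC5 to N and 2724, 0% higher (reversed), from N to NFD, and the changes at chromosome 1 from 201360590 and chromosome 5 from 139423147 reversed to 0.11 and -0.98 on the log2 scale.

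DESeq2 gave 125 H3K27me3 calls from MRC5 to N (407 at an unadjusted p under 0.05) and 0 sites of treatment by time (211). Limma with missing libraries gave 7030 NEUROG2 treatment calls (93.7% higher), 49 of treatment by time, 14842 (27.8% higher) and 10365 H3K27ac calls, and 0 and 0 for H3K27me3 (1487 and 1972 at an unadjusted p under 0.05). With all 6 lists as labelled, edgeR gave 0 H3K27me3 calls from MRC5 to N (49 at an unadjusted p under 0.05) and 6, 0% higher (reversed), from N to NFD (455). With the replicate block as well it gave 0 and 0 (61 and 539).

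With peaks at least 8-fold over input, NEUROG2 gave 311 treatment, 114 time and 0 treatment-by-time calls by edgeR (86 at an unadjusted p under 0.05) and 1288 sites mostly in 1 treatment. H3K27ac gave 459 and 316 calls, with 6697 regions gained or lost from MRC5 to N (41.0% gained, reversed) and 3242 from N to NFD. H3K27me3 gave 155 regions gained or lost from N to NFD (30.3% gained, reversed). Overlaps of NEUROG2 sites with H3K27ac of MRC5, N and NFD were 4.96%, 13.0% and 12.9% for N and 6.31%, 12.5% and 16.1% for NFD. With H3K27me3 they were 0.0212%, 0.414% and 0.0319% for N and 0.0362%, 0.353% and 0.0271% for NFD. Of SOX4 sites 10.8% overlapped NEUROG2. Replicate agreement was 75.2% for H3K27ac, 11.2% for H3K27me3 and 21.5% for SOX4.

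With an equal number of peaks per list, 67.7% of the sites mostly in 1 treatment were on the NFD side and 49.1% of the H3K27ac regions changed from N to NFD were gained. H3K27me3 gave 0 and 0 calls by edgeR (168 and 225 at an unadjusted p under 0.05) and 7383 regions gained or lost (28.1% gained, reversed), with an agreement of 40.0%. Overlaps of N sites with H3K27ac of MRC5, N and NFD were 24.2%, 53.7% and 62.4%, and of NFD sites with that of N and NFD 53.2% and 71.9%. With H3K27me3 they were 2.44%, 3.53% and 0.785% for N and 2.56%, 3.71% and 0.850% for NFD. Of SOX4 sites 29.2% overlapped NEUROG2.

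With the stricter overlap rule H3K27me3 gave 100 calls from MRC5 to N. N sites overlapped H3K27ac of MRC5, N and NFD at 24.6%, 63.3% and 60.6%, and H3K27me3 of MRC5 and NFD at 3.08% and 2.06%. NFD sites overlapped H3K27me3 of MRC5, N and NFD at 3.27%, 2.85% and 2.09%. With the merged lists, 51688 and 31730 H3K27ac regions were gained or lost, N sites overlapped H3K27ac of N and NFD at 57.9% and 54.0%, NFD sites that of MRC5 and NFD at 32.4% and 61.2%, and SOX4 sites overlapped NEUROG2 at 11.6%.

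Leaving out a library also loosens the rules for presence (4 of 5 libraries for NEUROG2, a single library for a histone group), so counts of sites mostly in 1 treatment and of regions gained or lost rise by construction. Leaving out each library in turn, NEUROG2 time calls ran from 448 (without NFD 2-day replicate 1) to 849, treatment-by-time calls from 0 to 1 by edgeR (469 to 766 at an unadjusted p under 0.05), and sites mostly in 1 treatment from 3760 to 5289 (without NFD 0.5-day replicate 2; 4836 without its replicate 1), with 74.8 to 88.0% on the NFD side. H3K27ac calls from N to NFD ran from 3576 (without NFD replicate 2) to 5653, and regions gained or lost from 19061 to 22034 (without N replicate 1; 21707 without N replicate 2). H3K27me3 calls from N to NFD were 436 without MRC5 replicate 1, and regions gained or lost were 31483 without NFD replicate 1 and 26618 without NFD replicate 2. N sites overlapped H3K27ac of MRC5 at 22.9 to 26.5%, of N at 53.8 to 69.4% and of NFD at 51.4 to 64.6%, and H3K27me3 of MRC5 at 3.03 to 3.07%, of N at 2.41 to 2.61% and of NFD at 2.22 to 3.08%. NFD sites overlapped H3K27ac of MRC5 at 28.9 to 32.1%, of N at 51.0 to 65.5% and of NFD at 54.8 to 69.6%, and H3K27me3 of MRC5 at 3.42 to 3.58%, of N at 2.49 to 2.66% and of NFD at 2.36 to 2.94%. SOX4 sites overlapped NEUROG2 at 29.9 to 35.0%.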

Other observations

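The tests of a technical difference between HA libraries and of background from opened or closed chromatin were chosen only after the result was seen.

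The molecules changed NEUROG2 tags at each time. Fitted by day, tags rose at 258 and fell at 218 shared sites at 0.5 days, rose at 495 and fell at 421 at 1 day, and rose at 443 and fell at 362 at 2 days by edgeR. From 0.5 to 2 days they rose at 125 and fell at 170 sites within N, and rose at 229 and fell at 222 within NFD. Whether more sites changed at one time than another was not tested beyond the interaction test.

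H3K27ac of NFD differed from that of MRC5 at 9983 shared regions, 4945 higher and 5038 lower by edgeR, and 16359 regions were gained and 17153 lost outright, against 396 and 457 in the crossed splits. From MRC5 to N, the median log2 fold change was 0.33 at the 4882 shared regions with a NEUROG2 site of N and -0.12 at the 10582 without. A site lay in 52.9% of the regions that rose, 24.6% of those that fell and 23.5% of those not called. From N to NFD, a NEUROG2 site of NFD lay in 59.0% of the regions that rose, 43.8% of those that fell and 41.1% of those not called. NEUROG2 sites of N lay in 37.9% of the regions that rose, 39.2% of those that fell and 27.2% of those not called, with a median log2 fold change of -0.05 at regions with such a site and 0.04 at those without.

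The treatment difference in NEUROG2 tags was larger than in other splits of the libraries. Of 100 splits that kept 2 and 2 libraries at each time, 1, the real one, called as many sites, with 1968 against at most 800 in the others. The same held for time (679 sites against at most 405, 1 of 100) and for sites called mostly in 1 treatment (3173 against at most 1851, 1 of 100). These splits regroup single libraries. If the libraries of a group shared a culture, the splits cannot exclude chance differences between cultures. A technical difference between the HA libraries of the treatments, if unrelated to chromatin, would leave their effects unrelated to H3K27ac in other libraries. The lowest correlation across sites in any pairing of single H3K27ac libraries was 0.459, which argues against that kind only. All pairings used the same NEUROG2 effects. A technical difference that follows open chromatin would correlate with H3K27ac as well, so this test cannot exclude it. Background from chromatin that opened or closed stays open: 32.0% of the sites at least 8-fold over input were called, against 35.3% of all, with median absolute log2 changes of 0.42 and 0.50, but fold over input does not bound what the antibody draws from open chromatin, and no precipitation from untagged cells was analysed here. A shift of NEUROG2 binding together with H3K27ac and such background therefore cannot be told apart.

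Sites favoured with the molecules lay more often in H3K27ac regions of untreated fibroblasts than sites favoured without them. Site strength does not account for this: after matching raised and lowered sites on mean tags the difference was 15.2 percentage points (95% bootstrap interval 11.3 to 19.4), against 16.3 unmatched. The bootstrap interval counts sites of a genome and not replicates, so it leaves out the spread between libraries. More peaks in the NFD libraries do not account for the difference either, since with equal lists the difference between sites mostly in NFD and mostly in N was 28.7 points. No biological explanation for this difference was tested.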
